A study of Mus musculus with 6 samples.

How the data were processed

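RNA was taken from the anterior presomitic mesoderm and the newest somites of mouse embryos at embryonic day 9.5, with C57BL/6J given as the strain for both genotypes. Per the labels' protocols, tissue of 5 embryos made a pool, 250 ng of total RNA with an RNA integrity number of at least 7.9 was reverse transcribed with Cy3 or Cy5, and 3 pools of each genotype were compared on 6 two-colour Agilent arrays. Spot intensity was read with Agilent Feature Extraction, version 10.7.3.1 for the arrays of slide 1 and 10.5.1.1 for those of slide 2 per the file headers, while the submitters' processing notes name version 8.5.1.1. The deposited series matrix holds the log10 ratio of Cy5 over Cy3 of each array, which differed from the log10 ratio in the scanner files by at most 5e-11. Its direction and scale were therefore known, and the median of every column was 0. Bright spots of slide 1 were saturated (between 79 and 486 spots per channel), whereas none was marked as saturated on slide 2.

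The median spot intensity and the median local background of both channels were corrected with normexp at an offset of 50 and normalized within each array by loess in limma 3.58.1 under R 4.3.3, with data.table version 1.17.8 for reading. The plan named mean spot intensities, but the columns for slide 2 hold medians, so medians were used on all 6 arrays. The 1639 control spots and the outlier spots had no weight in loess, outlier spots (438 to 620 per array) were left out, and replicate spots of a probe were averaged. Every ratio was turned to Paraxis-/- over WT, and both dye-swapped arrays of a pair were averaged, so that dye effects cancel and n is 3 pairs. The median absolute dye effect was 0.07 on the log2 scale, and it was above 1 for 6 genes. Levels of a pool are log2 values after loess and Aquantile normalization. Channels were tied to genotypes through the dyes in the labels.

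The titles and the first sentence of the descriptions disagree on the pools of 2 arrays, and the titles were used. This was checked by correlating, across genes, the deviations of each array from the mean of its dye orientation. Arrays with the same pair in their titles had r of 0.42, 0.63 and 0.64, and all other combinations lay between -0.44 and -0.12. Subtracting the mean by itself pushes the other combinations toward negative values. Without that step the same pairs had r of 0.37, 0.22 and 0.50, and the others lay between -0.14 and 0.05. The pools of a pair shared their arrays, so the pair is the replicate.

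Probes were kept when well above background in at least 4 of the 6 measurements of either genotype, which left 28639 of 41174 probes, and each gene was represented by its brightest kept probe. Names came from the first slide's files and were updated through a RefSeq gene listing of another build, used for names only. By accession 26690 probes matched, by symbol 5189 and by synonym 952, and 8343 kept the name in the file. Coordinates are those of the probes in the file headers' build, mm9, and whether a probe lies in an exon or an untranslated region is not annotated here. In all 19325 genes with at least 2 pairs were tested, 74 of them with fewer than 3 pairs. The pair ratios were tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The labels give the pools of a genotype as separate biological replicates.

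Before the data were examined, 37 gene lists were written, covering somite derivatives, somite polarity, signalling pathways, cell functions, axial level, other cell types and tissue handling. The 36 with at least 5 tested members were compared with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. Genes were named by a rule fixed beforehand. It took Tcf15, up to 12 genes in each direction with the same sign in all 3 pairs (those past the threshold by size, then those with the smallest p), and up to 4 members of each list with the smallest p. Genes known only by an accession or clone were counted and not named. Not all genes that the rule took, nor all lists, are named in the text, and the choice among members of a list was made after their values were seen. The region test drew 100000 random sets of tested genes.

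The fit was tested on simulated pairs for 19250 genes, with 50 changed genes at each of 4 sizes. Variances were drawn from the distribution fitted to the real genes. The fit recovered 18.0% of 1.5-fold, 70.0% of 2-fold, 98.0% of 4-fold and 98.0% of 8-fold changes, with 9 false calls among 151. With that many calls the cutoff on p is more lenient than in the real data, where 4 genes passed. These shares therefore do not give the power of the real comparison. In the real data Cpne8, 2.03-fold higher with an SE of 0.07, did not pass. Alternatives covered the background correction, the normalization within and between arrays, the filter on dim probes, the deposited ratios, the pairing and blocking of arrays, the slide, the variance model, the probe rule, the threshold, the window around Tcf15 and leaving out each pair. The slide coincides with the scan and the software version, and both genotypes are on each slide. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.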

Results

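Gene expression was compared between wild-type (WT) mouse embryos and embryos lacking Paraxis, the basic helix-loop-helix transcription factor encoded by Tcf15, which is known from mouse genetics to be needed for new somites to form an epithelium. The tissue was the front part of the presomitic mesoderm together with the 4 most recently formed somites at embryonic day 9.5. Somites are the segmental blocks of paraxial mesoderm that give rise to vertebrae, ribs, skeletal muscle and dermis. Tissue from 5 embryos was combined into a pool, and there were 3 pools of each genotype. Each WT pool shared 2 arrays with 1 Paraxis-/- pool, with the dyes exchanged on the second array, so that the 6 arrays gave 3 independent pairs of pools, called A, B and C after the WT pool. Of the 43379 gene spots on an array, between 27080 and 30982 were well above background in the WT channel and between 28683 and 31795 in the Paraxis-/- channel. Pair A was hybridised on slide 1 and pairs B and C on slide 2. The number of pairs limits the precision of every ratio below. All ratios are Paraxis-/- over WT on the log2 scale, given as the mean of 3 pairs with the standard error (SE) of the limma fit.

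The targeted gene came first, as a check of the labels and of the dye orientation. Tcf15 signal fell by 5.41 on the log2 scale (SE 0.09, n = 3 pairs, limma adjusted p = 0.00053), which is 42.5-fold lower in Paraxis-/- tissue. The log2 ratio was -5.23 in pair A, -5.48 in pair B and -5.52 in pair C. The mean log2 signal was 15.17 ± 0.11 (SD, n = 3 pools) in WT and 9.76 ± 0.05 (SD, n = 3 pools) in Paraxis-/- tissue, and the spot was still well above background in all 6 Paraxis-/- measurements. The 1 probe for this gene lies on chromosome 2 from 151974683 to 151974742 in mm9. The labels do not say which part of the gene was removed, so whether the probe lies inside it is not known here. An exact two-sided sign-flip test of the 3 pair ratios gave p = 0.25, the smallest value that 3 pairs allow.

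Beyond Tcf15, few genes passed the adjusted threshold with 3 pairs. Pax1, a paired-box transcription factor that marks the sclerotome, the part of the somite that forms vertebrae, fell by 4.35 (SE 0.13, adjusted p = 0.0046), or 20.4-fold. Snhg11, a long non-coding RNA that hosts small nucleolar RNAs, rose by 1.60 (SE 0.07, adjusted p = 0.0175), or 3.02-fold. A transcript that the files name only by an accession rose by 1.41 (SE 0.07, adjusted p = 0.0234), or 2.65-fold. With Tcf15 these made 4 genes past an adjusted p of 0.05 among the 19325 tested with limma, 2 higher and 2 lower in Paraxis-/- tissue. At an unadjusted p under 0.05 there were 979 genes, 452 higher and 527 lower, where chance alone gives 966. A ratio of at least 1.5-fold together with an unadjusted p under 0.05 was met by 90 genes, 39 higher and 51 lower, and 36 genes reached 1.5-fold in one direction in all 3 pairs. Across genes the pair log2 ratios correlated weakly, with Pearson's r of 0.11 between pairs A and B, 0.07 between A and C and 0.17 between B and C, and genes are not independent replicates. The count depended on the model and the scaling: slide as a block gave 76 genes, 39 of them higher, and scaling the ratios between arrays gave 18 genes, 4 higher and 14 lower. Within slide 2 alone, which holds pairs B and C, 2 genes passed, and slide 1 holds 1 pair and allows no test.

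All 4 genes past the threshold lie on chromosome 2 within 10 Mb of Tcf15. The Pax1 probe starts at 147200673, the Snhg11 probe at 158211554 and the probe of the transcript without a symbol at 156558546 in mm9. Zcchc3, a zinc-finger protein that binds nucleic acids, lies 0.264 Mb from Tcf15 and had a log2 ratio of -1.09 (SE 0.08, adjusted p = 0.125). Rprd1b, a protein that binds the tail of RNA polymerase II, lies 5.93 Mb away and had a log2 ratio of -1.48 (SE 0.14, adjusted p = 0.178). Probes of these genes did not all give the same size of change. A dimmer Pax1 probe had a log2 ratio of -0.32 and was not well above background in any of the 6 Paraxis-/- measurements, a further Rprd1b probe well above background in all 6 measurements of each genotype had -0.12, and the 5 Snhg11 probes ran from 0.41 to 1.60. Leaving out pair B ended the calls of Tcf15 (log2 ratio then -5.37) and Pax1 (-4.44, adjusted p = 0.234), with fewer pairs to test, and both passed without pair A or pair C. Snhg11 and the transcript without a symbol did not pass with any 1 pair left out; the log2 ratio of Snhg11 was then 1.58, 1.62 and 1.59 without A, B and C. Averaging the probes of a gene also ended the call of Snhg11, at 0.90, and gave -2.34 for Pax1, still past the threshold, while Agilent processed signals gave -5.27 for Pax1.

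**Figure D1:**
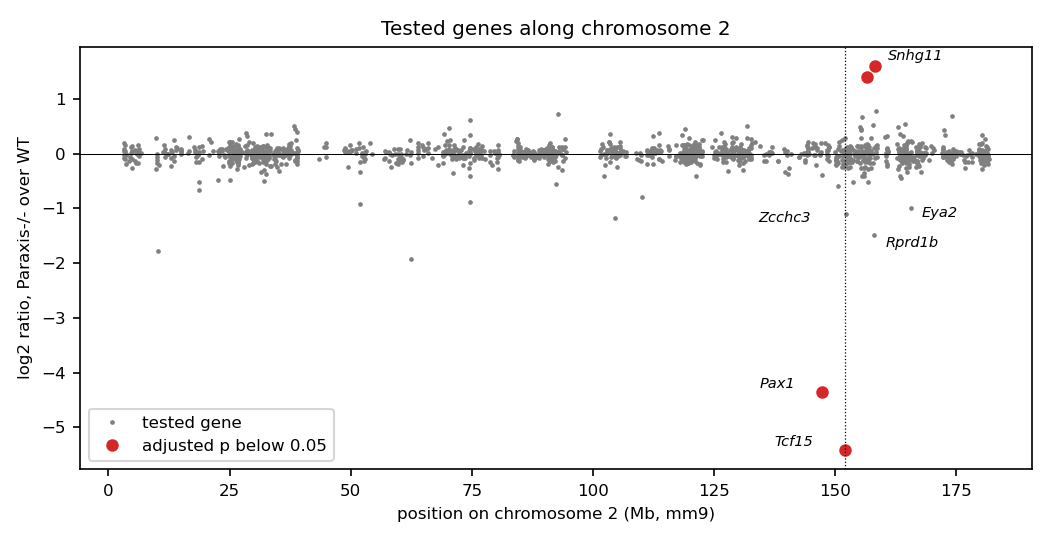
Log2 ratio of Paraxis-/- over WT (mean of 3 pairs) for each tested gene against the position of its probe on chromosome 2 in Mb of mm9; red points passed an adjusted p of 0.05 and the dotted line marks Tcf15. Tcf15 at -5.41, Pax1 at -4.35, Snhg11 at 1.60 and a transcript without a symbol at 1.41 lie close together near the distal end.

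The region around the targeted gene was compared with the rest of the genome by a permutation test. The 213 tested genes within 10 Mb of Tcf15, without Tcf15 itself, had a median absolute log2 ratio of 0.09, against 0.07 for the 18999 genes elsewhere. A one-sided permutation test with 100000 random draws of as many genes gave p = 4.00e-05. The draws treat genes as separate units, though genes are not independent replicates. This p and those below therefore measure a spread over genes and not over pairs of pools. Of the 213 genes, 7 met an unadjusted p under 0.05 with at least 1.5-fold, 3 higher and 4 lower, which is 3.29%, against 82 genes or 0.432% elsewhere (one-sided permutation p = 2.00e-05). Without pair B the median was 0.0903 near Tcf15 and 0.0884 elsewhere, and it no longer stood apart (permutation p = 0.405). The number of nearby genes with at least 1.5-fold in one direction in every remaining pair was then 5, against 58 elsewhere (permutation p = 0.00051).

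Regulators of the somite were among the other genes with large negative ratios. Meox2, a homeobox gene of somites and limb muscle, had a log2 ratio of -1.59 (SE 0.15, adjusted p = 0.186). Eya2, a transcriptional cofactor of sine oculis homeobox proteins in muscle precursors, had -1.002 (SE 0.09, adjusted p = 0.178), and its probe lies 13.6 Mb from Tcf15. Further negative ratios were those of Itih5, a hyaluronan-binding matrix protein (-1.78), Tdrd7, a tudor-domain protein of RNA granules (-1.40), Nrtn, the neurotrophic ligand neurturin (-1.33), and Lrmp, a membrane protein of the endoplasmic reticulum (-1.29). Each of these 6 genes had the same sign in all 3 pairs, and their limma adjusted p lay between 0.128 and 0.189, so none passed over all genes in this fit. Each passed in 4 or 5 of 17 alternatives, including a fit that counts technical dye swaps as replicates. Over the alternatives the log2 ratio of Eya2 ran from -1.77 to -0.94.

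Genes with positive ratios outside the Tcf15 region had varied functions. Etv2, an ETS transcription factor needed for endothelial and blood progenitors, had a log2 ratio of 1.54 (SE 0.12, adjusted p = 0.125). Cldn11, a claudin of tight junctions, had 1.07, Cpne8, a calcium-dependent membrane-binding copine, had 1.02, and Rflna, a filamin-binding protein, had 1.0002. Penk (0.80) and Cck (0.56) encode the neuropeptide precursors proenkephalin and cholecystokinin, and Ngfr (0.64) encodes the low-affinity neurotrophin receptor. Gadd45b, a growth-arrest gene induced by stress, had 0.77, the forkhead gene Foxo6 had 0.75, the orphan receptor Gprc5c had 0.74, and Nbl1, a secreted BMP antagonist, had 0.59. All 11 had the same sign in 3 pairs, and their adjusted p lay between 0.0978 and 0.348, so none passed over all genes in this fit. Each passed in 2 to 7 of 17 alternatives. For Foxo6, Nbl1, Ngfr, Cck and Gadd45b these were the 2 fits on 6 arrays. The fit without a replicate block counts technical dye swaps as replicates. Cpne8 passed in 7, among them Agilent processed signals, where its log2 ratio was 1.73 (limma adjusted p = 0.0295). The series matrix values hold nearly identical ratios, gave 1.73 too and are no separate support.

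**Figure D2:**
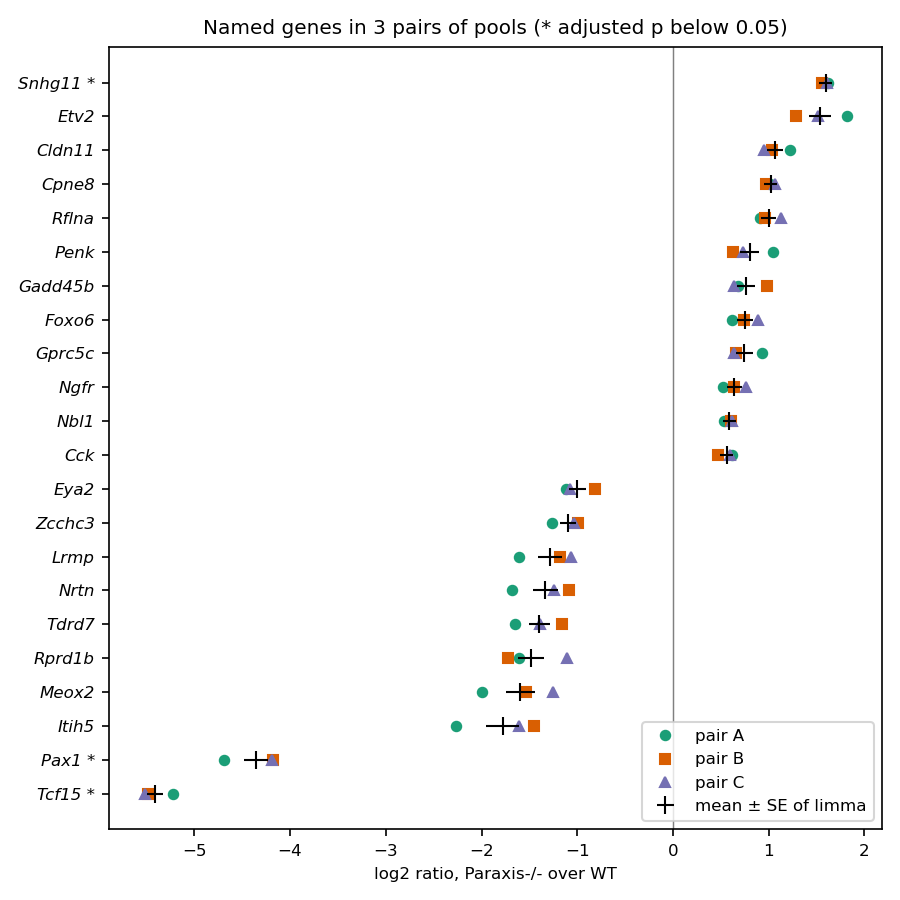
Log2 ratio of Paraxis-/- over WT for Tcf15 and for named genes with the same sign in all 3 pairs, chosen by size or p over all genes, in pairs A, B and C (coloured points), with the mean and SE of the limma fit in black; asterisks mark an adjusted p below 0.05. Ratios run from -5.41 for Tcf15 to 1.60 for Snhg11.

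Fixed lists of genes were then tested for a shift against all other genes, to ask which parts of the somite programme and which other tissues differed. Of the 36 lists with at least 5 tested members, 10 passed an adjusted p of 0.05 in camera with its preset correlation. Of these, 6 were shifted toward higher and 4 toward lower ratios. With the sign of pair A or of pair B turned, camera still called 8 lists. With a correlation estimated from the data none of the 36 passed, the smallest being adjusted p = 0.734 with an estimated correlation, and in the rotation test fry, which asks for a shift in one direction from no change and not against other genes, none passed either (smallest adjusted p = 0.103). At an unadjusted p under 0.05 there was 1 list with the estimated correlation and 4 with fry. The mixed test of fry, which asks for differences from no change in either direction, passed 4 lists: the sclerotome, the hypoxia and the BMP and TGF-beta lists (adjusted p = 0.0268 each) and the caudal somite list (adjusted p = 0.0361). Slide as a block gave 16 lists.

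The list of sclerotome and tendon precursor genes was shifted toward lower ratios in Paraxis-/- tissue. Adjusted over the list alone, 4 of its 18 tested members fell and 1 rose, and over all genes only Pax1 passed. Besides Pax1, the members that fell included Tbx18, a T-box gene of the rostral somite (log2 ratio -1.02, SE 0.11), and Uncx, a homeobox gene of the caudal somite (-0.78, SE 0.08). Scx, the bHLH gene of tendon precursors, rose by 0.34 (SE 0.09) by the same measure. The median log2 ratio of the list was -0.15, with pair medians of -0.14, -0.08 and -0.07. Over 17 alternatives the list median ran from -0.17 to -0.05. Its adjusted p was 0.00027 in camera, and adjusted p = 0.734 with an estimated correlation. Without the genes within 20 Mb of Tcf15 the camera adjusted p was 0.0048.

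Genes of the dermomyotome, the epithelial part of the somite that forms muscle and dermis, were also shifted toward lower ratios. Adjusted over the list alone, 5 of the 18 tested members fell and none rose, and over all genes none passed. These were Eya2, Meox2, Dmrt2, a regulator of the early myotome (-1.51, SE 0.20), Pax3, the paired-box gene of muscle precursors (-0.49, SE 0.09), and Sim1, a bHLH-PAS factor of the lateral dermomyotome (-0.26, SE 0.07). Sim1 lies outside the rule for named genes and was chosen after its value was seen. The list had a median of -0.09 and an adjusted p of 0.0012 in camera, against adjusted p = 0.734 with an estimated correlation. Without pair A the median was 0.01 and the camera call ended. Structural genes of muscle had a median of -0.03 and no call (camera adjusted p = 0.911).

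Genes of the rostral and caudal parts of each somite were counted as lists of their own. Among 9 rostral genes Tbx18 fell, adjusted over the list alone, and the list median was -0.06 (camera adjusted p = 0.0676). Among 12 caudal genes 2 fell, adjusted over the list alone, Uncx among them, while 9 of the 12 mean ratios were positive, among them Efnb1, an ephrin ligand (0.25), and the list median was 0.10 (camera adjusted p = 0.951). Over all genes no member of these lists passed. The Notch and segmentation clock list, 19 tested members that drive periodic somite formation, had a median of 0.00 (camera adjusted p = 0.911). Its member with the smallest p was Heyl, a Notch target, with a log2 ratio of -0.83 (SE 0.16), which did not pass over the list alone.

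The cellular functions attached to Paraxis by its epithelial role showed little shift. The list of adhesion and polarity genes (36 tested) had a median of 0.04, the integrin and basement membrane list (26 tested) -0.04 and the list of regulators of transitions between mesenchyme and epithelium (16 tested) -0.01. No member of these lists passed over all genes or adjusted over the list alone, and their camera adjusted p ran from 0.236 to 0.816. Their members with the smallest p included Col4a1, a basement membrane collagen (-0.44, SE 0.11, with 1 of its 2 tested probes of this sign), and Twist2, a bHLH factor of mesenchyme (-0.73, SE 0.18). In the interstitial matrix list Fap, a cell-surface protease of fibroblasts, fell by 1.92 (SE 0.28) adjusted over the list alone. Its Paraxis-/- signal was well above background in only 2 of 6 measurements, so the size of this ratio is uncertain, and alternatives ran from -4.02 to -1.37. Fbn2, a fibrillin of embryonic microfibrils, had -0.39. The matrix list had a median of -0.05 (34 tested, camera adjusted p = 0.292). In the list of bHLH relatives of Paraxis, 12 tested, Tal1 and Scx rose and Twist2 fell, adjusted over the list alone, none passed over all genes, and the median was -0.02 (camera adjusted p = 0.974).

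Signalling lists held single genes that differed. Aldh1a2, the enzyme that makes retinoic acid in somites, fell by 0.82 (SE 0.11) adjusted over its list alone, while the 13 retinoic acid genes had a median of 0.03 (camera adjusted p = 0.974). In the BMP and TGF-beta list (16 tested) the secreted ligands Tgfb2, up by 0.48 (SE 0.06), and Bmp7, up by 0.34 (SE 0.07), rose over the list alone, and the median was 0.09 (camera adjusted p = 0.116). The Wnt list (18 tested, median 0.14, camera adjusted p = 0.108), the FGF list (14 tested, median 0.10, camera adjusted p = 0.338) and the hedgehog list (12 tested, median -0.02, camera adjusted p = 0.918) had no member past either adjustment. Apcdd1, a Wnt inhibitor and target, had a log2 ratio of 0.32 with 1 of its 2 tested probes of this sign, and Ptch1, the hedgehog receptor, had 0.29. Over all genes no member of these 5 lists passed.

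Markers of other cell types that a dissection of this region could hold were shifted in several lists. The primitive blood list was the most shifted, with a median of 0.49 over 15 tested members (camera adjusted p = 1.02e-06, adjusted p = 0.734 with an estimated correlation). Adjusted over the list alone, Tal1, the bHLH master regulator of blood, rose by 0.80 (SE 0.11), and over all genes none passed. The globin genes Hba-a1 (0.67, SE 0.22) and Hba-x (0.55, SE 0.19) and the heme enzyme gene Alas2 (0.70, SE 0.25) did not pass over the list alone. The list median was 0.49 in pair A, 0.87 in pair B and -0.08 in pair C, and over 17 alternatives it ran from 0.26 to 0.79. Among 16 endothelial genes Etv2 rose adjusted over the list alone, the VEGF receptor gene Kdr had 0.44 (SE 0.15), and the list median was -0.07 (camera adjusted p = 0.951). Surface ectoderm genes had a median of 0.17 (13 tested, camera adjusted p = 0.0024, adjusted p = 0.734 with an estimated correlation), with Wnt6 at 0.22 and the keratin gene Krt5 at 0.17. Gut endoderm genes had a median of 0.20 (10 tested, camera adjusted p = 0.0184, adjusted p = 0.787 with an estimated correlation), with the endoderm factor Sox17 at 0.29 and the alpha-fetoprotein gene Afp at 1.91 (SE 0.85), whose pair ratios were 4.34, 1.58 and -0.20. Afp was well above background in only 4 of 6 WT measurements, so the size of its ratio is uncertain. No member of the ectoderm and endoderm lists passed either adjustment, and without pair A both camera calls ended, at medians of 0.03 and 0.04.

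No other tissue list passed. Neural tube genes had a median of -0.07 (17 tested, camera adjusted p = 0.409), with pair medians of -0.76, 0.16 and 0.11. Neural crest genes had 0.01 (10 tested, camera adjusted p = 0.911), notochord and floor plate genes 0.08 (8 tested, camera adjusted p = 0.547) and intermediate mesoderm genes 0.03 (11 tested, camera adjusted p = 0.547). In the lateral plate and limb bud list Tbx5, a T-box gene of the forelimb field and heart, rose by 0.50 (SE 0.08) adjusted over the list alone, and the median was 0.04 (14 tested, camera adjusted p = 0.193). Over all genes no member of these 5 lists passed.

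Genes that mark position along the body axis and the age of the paraxial mesoderm formed 3 further shifted lists. Hox genes of paralogue groups 1 to 5, which are expressed from more anterior levels, had a median of 0.13 (15 tested, camera adjusted p = 0.0042, adjusted p = 0.787 with an estimated correlation), with Hoxd4 at 0.62 and Hoxb5 at 0.25. Those of groups 6 to 13 had a median of -0.14 (18 tested, camera adjusted p = 0.0052, adjusted p = 0.734 with an estimated correlation), with Hoxa11 at -0.92 and Hoxd11 at -0.40. Hoxd11 was well above background in only 3 of 6 Paraxis-/- measurements, and its alternatives ran from -1.42 to -0.22. The call of groups 1 to 5 ended without pair A (median 0.08, camera adjusted p = 0.307), and that of groups 6 to 13 without pair C (median -0.05, camera adjusted p = 0.125). Across the 33 Hox genes, which are not independent replicates, the log2 ratio and the paralogue number had a Spearman correlation of -0.73 and Pearson's r of -0.64 (permutation p = 1e-05 for the former, the smallest that 100000 draws give, adjusted p = 2.33e-05 over 7 such relations). The Spearman correlation was -0.74 in pair A, 0.03 in pair B and -0.63 in pair C. Genes of the posterior presomitic mesoderm had a median of 0.22 (20 tested, camera adjusted p = 0.0047, adjusted p = 0.836 with an estimated correlation), with the Wnt target Sp5 at 0.46 and the retinoic acid degrading enzyme gene Cyp26a1 at 0.37. Their pair medians were 0.79, -0.21 and 0.09, and without pair A the median was -0.10, with a call toward lower ratios (camera adjusted p = 0.039). No member of these 3 lists passed over all genes or adjusted over the list alone.

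**Figure D3:**
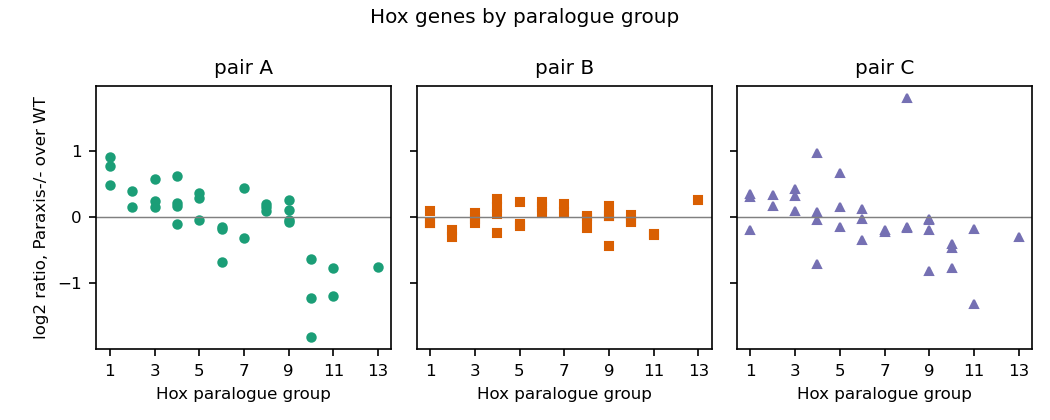
Log2 ratio of Paraxis-/- over WT for each of 33 Hox genes against its paralogue group, with 1 panel for each pair of pools. Ratios fall with paralogue group in pair A (Spearman correlation -0.74) and pair C (-0.63), and not in pair B (0.03).

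Housekeeping and tissue-handling lists gave the remaining values. Ribosomal protein genes had a median of -0.14 (19 tested, camera adjusted p = 0.0054, adjusted p = 0.787 with an estimated correlation), with Rpl19 at -0.25, Rps14 at -0.30 and pair medians of -0.39, 0.05 and -0.05. On slide 1, which is pair A, 16 of the 19 members had saturated spots, Rpl19 and Rps14 among them, so their ratios are not reliable, and the 3 members without saturation were too few to test. Its call ended in 4 of 17 alternatives, among them without pair A, where the median was -0.01 (camera adjusted p = 0.853). Immediate early and heat shock genes had a median of 0.06 (14 tested, camera adjusted p = 0.0076, adjusted p = 0.734 with an estimated correlation), with Egr1, an immediate early transcription factor, at 0.40 and Btg2, an antiproliferative p53 target, at 0.36 (SE 0.12). Only 1 of the 3 tested Btg2 probes had this sign, and Btg2 turned to -0.05 with Agilent processed signals and with the series matrix values. The call of this list ended in 3 of 17 alternatives, among them without pair B, where the median was 0.04 (camera adjusted p = 0.0571). The lists for hypoxia and glycolysis (14 tested, median 0.12, camera adjusted p = 0.0768), unfolded protein and amino acid stress (11 tested, median -0.07, camera adjusted p = 0.782) and the cell cycle (20 tested, median 0.05, camera adjusted p = 0.292) were not called. In the p53 and apoptosis list (15 tested, median -0.02, camera adjusted p = 0.911) Trp53inp1, a p53 target, rose by 0.54 (SE 0.08) adjusted over the list alone, and Trp53 itself had -0.30. No other member of these 6 lists passed over the list alone, and none passed over all genes.

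**Figure D4:**
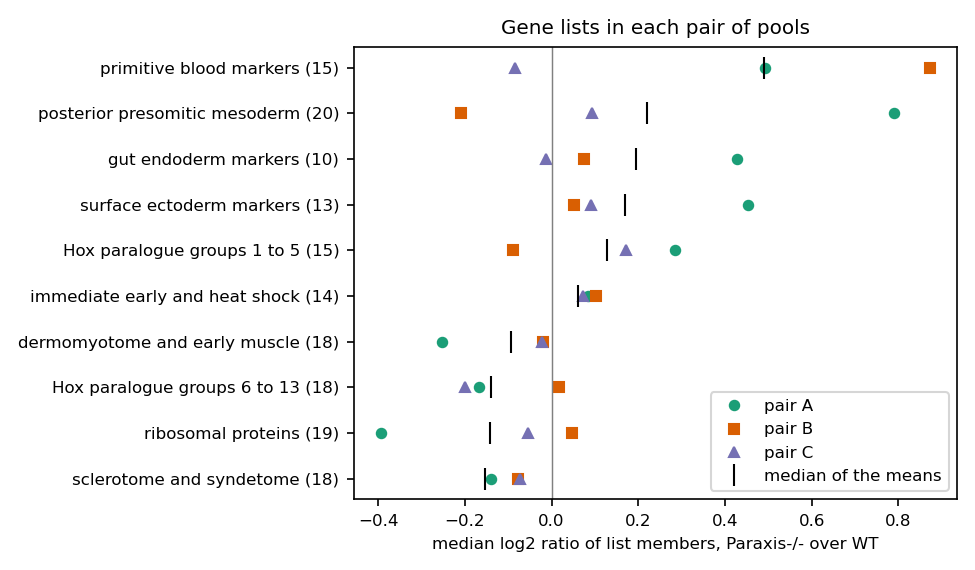
Median log2 ratio of Paraxis-/- over WT over the tested members of the 10 lists called by camera, in pairs A, B and C (coloured points) and for the mean of the pairs (black); the number of members is in parentheses. The blood list lies at 0.49, 0.87 and -0.08 in the 3 pairs, and the sclerotome list lies between -0.14 and -0.07.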

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

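Leaving out genes near Tcf15 or with saturated spots, the count of genes in 3 pairs and the omission of pairs for the region were chosen after the results were seen, and the estimated correlation and fry were added to the alternatives then, though the design named both; the others were planned. Against 4 genes, 18 passed after scaling between arrays, 10 with a variance trend and robust eBayes, 76 with slide as a block, 69 with no replicate block (6 arrays as replicates) and 40 with the replicate block as a random effect. The fit with no replicate block counts technical dye swaps as replicates. Slide as a block gives pair A, alone on slide 1, as much weight as pairs B and C together. Its residual spread comes from B against C only, so a difference in pair A alone can pass. Of its 76 genes 39 were higher, among them Prl2c5 (2.72), Prl8a2 (2.68) and Hbb-bt (2.35), chosen after their values were seen. Their source was not tested, nor was the cause for the other settings. A lenient threshold (unadjusted p with 1.5-fold) gave 90, and 1.5-fold in all 3 pairs gave 36. Without genes within 20 Mb of Tcf15 limma called 0 genes (926 at an unadjusted p under 0.05, smallest adjusted p 0.251). Leaving out 1 pair gave between 0 (without pair B) and 2 genes, with fewer pairs to test. The other settings gave 3 to 6 genes, and unpaired pools gave 3, all of them among the 4. Tcf15 lay between -5.50 and -5.35 with 1 pair left out; without pair B its limma adjusted p was 0.0872, and it passed in all other settings. Lists numbered 10, against 16 with slide as a block, 0 with an estimated correlation and 0 with fry in one direction, and 9 to 12 elsewhere. Of the 10, only 5 were among the 11 lists without pair A and 7 among the 9 with median centring. The 5 include the posterior presomitic mesoderm list, which without pair A was called in the opposite direction. Without the 387 genes with a saturated measurement 10 lists passed, 9 of them shared: the ribosomal list could not be tested, and the hypoxia list passed (camera adjusted p = 0.0107). The median absolute ratio near Tcf15 was 0.1005 within 5 Mb and 0.0941 within 20 Mb, and with 1 pair left out it lay between 0.0903 (without pair B, permutation p = 0.405) and 0.0977. The posterior presomitic mesoderm list turned to -0.10 without pair A (0.41 without pair B). Without pair B Xist turned to 0.42 and Eif2s3y to -0.44, against -1.24 and 1.23 without pair C. Btg2 turned from 0.36 to -0.0514 with Agilent processed signals and to -0.0514 with the series matrix values, which hold nearly identical ratios and are no separate result. The brightest probe was chosen anew in each setting, and whether a change of probe was the cause was not tested. Pairing the arrays by the descriptions gave 5 genes, including the 4. Signal over background limits Pax1, whose dimmer probe gave no Paraxis-/- level.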

Other observations

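The tests of explanations for the Tcf15 region, the blood list and the Hox genes were chosen after the results were seen, except that the design already held the comparison within 10 Mb, whose use as a test of a flanking segment was written later, and the count over other splits of the pairs. Some sex-linked genes had opposite signs in pairs B and C. Xist, the RNA that coats the inactive X chromosome, had a log2 ratio of -2.40 in pair B and 0.92 in pair C, and the Y-linked gene Eif2s3y had 2.24 and -1.10. In pair A they had -0.08 and 0.22. Both genes were chosen after their values were seen. Of the 6 other tested members of their list, 3 kept the same sign in pairs B and C, with small ratios in pair C. These were Eif2s3x (-0.49 and -0.07), Kdm5c (-0.30 and -0.04) and Zfy1 (0.20 and 0.03). The Y-linked gene Kdm5d turned from 1.23 in pair B to -0.27 in pair C. Whether the pools of these pairs differed in the sex of their embryos was not tested. In pair B the X-linked genes named here were lower and the Y-linked ones higher. The list of sex-linked genes had a median of 0.05 over 8 tested members, with no member past either adjustment (camera adjusted p = 0.951). Because the list holds both X-linked and Y-linked genes, its median and a test for a shift in one direction cannot show a difference in sex.

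Turning the sign of 1 pair at a time gives 4 splits of the 3 pairs with the real one, too few for a share under 0.05. The real split gave 4 genes and the highest other gave 0, so that 1 of the 4 splits gave as many. At least 1.5-fold in all 3 pairs was met by 36 genes in the real split and at most 7 in the others, an unadjusted p under 0.05 with 1.5-fold by 90 and at most 56, and an unadjusted p under 0.05 by 979 and at most 817. For the lists the real split gave 10, again 1 of 4 splits with as many, and turning pair A, B or C gave 8, 8 and 3. Camera at its preset correlation thus called nearly as many lists with pair A or pair B turned. The count of 10 lists is therefore little evidence of a difference between the genotypes.

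The first pattern is that the genes past the threshold lie near Tcf15. A local effect of the targeted allele within 1 Mb would leave no excess further out, but 6 of the 181 genes between 1 and 10 Mb met an unadjusted p under 0.05 with at least 1.5-fold (permutation p = 0.00015), and matching on mean intensity did not remove the excess within 10 Mb (permutation p = 1.00e-04), which argues against dim probes. A flanking segment of another strain, kept around the targeted allele during breeding, is a candidate explanation. The median absolute ratio within 10 Mb stood apart (permutation p = 4.00e-05, though permutation p = 0.405 without pair B). All these permutation p-values are over genes, which are not independent replicates, and not over pairs of pools. Genes with an unadjusted p under 0.05 made up 16.1% within 5 Mb, 12.5% from 5 to 10 Mb and 20.9% from 10 to 15 Mb. Further out they made up 1.82% from 15 to 20 Mb and 6.28% from 20 to 30 Mb. Among all genes outside the 10 Mb window the share was 4.97%. Mismatch of probes to such a segment would lower signals only, and 3 of the 7 nearby genes were higher in Paraxis-/- tissue, Snhg11 with 5 of 5 probes; for the lower genes it cannot be told apart from lower expression, since the second Rprd1b probe had -0.12 while both Pygb probes had about the same ratio, -0.59 and -0.55 (Pygb was chosen after its value was seen). The strain in which the allele was made is not given in the labels, and regulation of Pax1 and its neighbours by Paraxis itself stays open and untested.

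The second pattern is the higher blood list. A lower share of paraxial cells would raise all other tissues alike. The blood median exceeded the neural tube median by 0.56, against a pooled SD over members of 0.31. In pairs A, B and C the medians were 0.49, 0.87 and -0.08 for blood and -0.76, 0.16 and 0.11 for the neural tube. The order was thus reversed in pair C, and the SD is a spread over genes and not over pools, so the comparison cannot decide. More blood cells in the Paraxis-/- pools of pairs A and B may account for the higher blood list, and the test left this open. Of 5 globin and heme genes, 3 were higher by at least 0.2 in pair A and all 5 in pair B, so 3 were higher in both pairs. Hbb-y (0.07) and Hbb-bh1 (0.06) were not in pair A, and in pair C 1 of 5 was. These 2 embryonic globin genes were chosen after their values were seen. Hbb-bh1 was saturated in 1 WT and 2 Paraxis-/- measurements, all on slide 1, so its ratio in pair A is not reliable. A change in blood progenitors of the mutant stays open too, with Tal1 higher in pairs A, B and C by 0.84, 1.01 and 0.54.

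The third pattern is the slope of Hox ratios along the paralogue groups. More anterior or younger tissue in the Paraxis-/- pools of all 3 pairs is argued against by pair B, where the Spearman correlation was 0.026, and a single outlying pair by the weakest correlation of -0.59 with 1 pair left out. Another axial level or stage of the pools in some pairs stays open. The difference between pairs A and B followed the paralogue number (Spearman correlation -0.73 over 33 genes), but this restates the values of the 2 pairs and decides nothing. An effect of genotype that varies between pools was not tested.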
